A study of Mus musculus with 17 samples.

How the data were processed

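Pancreatic cells of 17 mouse libraries in 12 groups were profiled by a modified STRT-seq protocol, which counts molecules of single cells with unique molecular identifiers (UMIs). Per the labels' protocols, cells expressing RFP were sorted from Ngn3-Cre; Rosa-RFP mice and transferred into lysis buffer by mouth pipette. RNA was reverse-transcribed and amplified over 18 PCR cycles, followed by 4 cycles with indexed primers. Per the labels, adult male mice aged 2 months received 1 intraperitoneal dose of streptozotocin (STZ) at 200 mg/kg after an overnight fast, and age-matched controls received citrate buffer.

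The deposited UMI table held counts of 40824 genes in 2999 cells, all of which were assigned to a library by the cell names. The authors also deposited a table of signal values for the same cells. Each nonzero value there equalled the UMI count times 100000 over the cell's UMI total without 8 genes (Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Pyy and Yam1), within a tolerance of 0.01. A further deposited table, of another kind, gave the name of each cell's raw read file, from which sequencing runs were read for 10 libraries. Per the submitters' processing notes, TopHat2 2.1.0, featureCounts 1.5.3, SAMtools 1.3.1 and UMI-tools 0.5.0 were used with the mm10 genome. The notes give neither their order nor any filter on cells. The table held 0 mitochondrial genes by symbol, and the lowest cell had 7751 UMIs. No cell was left out here.

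Cell types were assigned here. Cells were clustered on 300 variable genes, 15 principal components and 20 nearest neighbours (Python 3.11.15, NumPy 2.4.6, scikit-learn 1.9.0) by the Leiden method (leidenalg 0.10.2, igraph 0.11.9). A first resolution of 0.03 was followed by 0.1 within clusters of at least 600 cells of a class other than beta. Beta-cell clusters were not split again. The 10 clusters were named by marker lists written before the data were examined, as were the gene lists, the tests, the alternatives and the rule for named genes. Clusters of the same class were joined, and 1 cluster of 59 cells stayed unnamed. Cell classes are called beta, alpha, delta, PP, acinar, ductal and immune cells below, by their markers alone. UMIs were then summed per library and class.

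Beta and alpha cell sums were compared with edgeR 4.0.16 under R 4.3.3. TMM scaling, filterByExpr and the quasi-likelihood F test without robust estimation were used, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The comparison of the 8 STZ libraries from mice with insulin implants against the 3 controls used only these libraries, with 1 mean per arm. Day 12, every other time point, month 2 without implants and the contrast of month 2 without against with implants came from 1 fit with a mean for each of the 12 groups. A group with 1 library was assumed there to vary like the replicated groups. The trend over time used log2 of days after STZ, with 30 days taken for a month. STZ_D6 was taken as day 6 by its name, although the series text also speaks of day 1 for it, and the rank of time, which is the same for either day, was tried as an alternative. Postnatal libraries were compared with adult controls as 1 arm of 4. A separate contrast of P12 and P21 against P3 was used for the correlation of fold changes across genes, since it shares no library with the STZ comparison. Alpha cells were compared in libraries with at least 10 alpha cells. The difference of the STZ effect between beta and alpha cells was tested with the library as a block, in libraries with at least 10 cells of each type. These were 7 STZ libraries and 2 controls, without STZ_M2, which held 9 beta cells. Errors of log2 fold changes were derived from the quasi-likelihood F test, as the absolute log2 fold change over the square root of F. They restate that test and are no separate measure of precision. Means of log2 CPM (UMI counts of a gene scaled by the library total; prior count 2) are given with the SD over libraries.

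The share of beta cells was taken over beta, alpha, delta and PP cells, with exact Clopper-Pearson intervals at 95%. An identity score averaged log2 CPM plus 10 over 17 beta-cell maturity genes, after each cell was thinned to 30449 UMIs, the 10th percentile of beta cells. Cells below that depth were left out of the score. Shares and scores were compared by exact two-sided permutation tests over libraries (SciPy 1.17.1).

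The 23 gene lists covered insulin granule and hormone processing, beta-cell transcription factors, glucose sensing and secretion machinery, beta-cell maturity, immature, progenitor and dedifferentiation genes, and genes disallowed in beta cells. Others covered the unfolded protein response, ATF4 and CHOP targets, the p53 and DNA damage response, the oxidative stress response, oxidative phosphorylation, glycolysis, cholesterol synthesis, cell division, and cytosolic ribosomal proteins. The remaining lists held antigen presentation and interferon response genes, immediate early and dissociation genes, and markers of alpha, delta, PP, acinar and ductal cells and of endothelial, stromal and blood cells. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Members were counted as called over all genes tested and adjusted over the list alone.

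Named genes followed a rule. It took a fixed set (Ins1, Ins2, Iapp, Gcg, Sst, Ppy, Ucn3, Mafa, Slc2a2, Pdx1 and Nkx6-1). It added up to 10 called genes per direction with the largest fold change, an average of at least 4 log2 CPM and the same direction in every library of the compared arm. It also added up to 4 called members per list with the smallest adjusted p. A gene outside the rule is said to have been chosen after its values were seen. Mafa had 0 UMIs in the beta cells of all 17 libraries, so it was not tested. A fold against 0 UMIs in a group is given as a lower bound against 3 UMIs over that group. With 1 to 3 UMIs, the ratio is given with its exact counting interval.

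Alternatives were RLE scaling, TMM without hormone genes, no low-count filter, a minimum average of 4 log2 CPM, DESeq2 1.42.0, limma-trend on means over cells, and the batch number of the labels as a block. Libraries with few cells were also left out, as was each library in turn. Over 12 pairs of libraries from different groups with the same number, deviations from group means correlated across genes with a median r of 0.036 (-0.0996 to 0.108). In groups of 2 libraries the deviations mirror each other. The median of -0.0205 over the 18 pairs with different numbers is therefore no separate reference. The main fits did not pair libraries by number, and these correlations cannot settle whether the numbers pair them. The fits were tested on simulated data with 200 changed genes, all drawn from genes with an average of at least 4 log2 CPM. Of 67 genes changed 4-fold, 65 were recovered between STZ and control beta cells, 51 at day 12 and 56 in alpha cells. Gene coordinates were taken from GENCODE M21 on GRCm38. Delta and PP cells were not compared between STZ and control. The controls held 7, 11 and 0 delta cells and 5, 7 and 0 PP cells, and the minimum of 10 cells per library set for these types before the data were examined left fewer than 2 controls. Beta cells were compared without such a minimum, except in the difference between beta and alpha cells.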

Results

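Single pancreatic cells were collected from mice treated with streptozotocin (STZ), a toxin taken up by insulin-producing beta cells, and from controls and young mice. The stated purpose was to describe endocrine cells after a single high STZ dose of 200 mg/kg and to use postnatal mice to judge the maturation of beta cells. The 17 libraries fell into 12 groups. Adult controls had 3 libraries. STZ with insulin implants was sampled at days 6, 12, 30 and 42 and at months 2, 5 and 9 (STZ_D6 to STZ_M9), with 2 libraries at day 12 and 1 at each other time. The implants of the month 9 mice were discontinuous in the last 2 months, per the labels. STZ without implants at month 2 (STZ_M2_NoIns) had 2 libraries, and postnatal days 3, 12 and 21 (P3, P12 and P21) had 1, 2 and 1. Nothing in the labels says whether replicates came from separate animals.

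The libraries held between 22 cells (control replicate 3) and 295 cells (control replicate 1). Their totals ran from 1420536 UMIs in control replicate 3 to 26298456 in STZ_D30, and the median cell held 61193 UMIs. The median per cell was lowest in STZ_D12 replicate 1 (36134 UMIs) and highest in STZ_D30 (77147). Cells separated by markers into 2 beta-cell clusters (896 and 131 cells), 2 acinar clusters (338 and 315), and clusters of 651 alpha, 273 delta, 188 PP, 101 ductal and 47 immune cells, with 59 cells left unnamed. The main beta-cell cluster of 896 cells was led by Ucn3, Prlr, G6pc2, Prss53, Ins1, Bace2, Slc2a2, Cox6a2, Ins2 and Iapp, several of which are compared below. A second beta-cell cluster of 131 cells was led by Nrep, Dlk1 and Nnat and held 129 cells of P3. Beta cells numbered 210, 139 and 21 in the controls, between 9 (STZ_M2) and 68 (STZ_M5) in the STZ libraries with implants, and 5 and 11 without implants.

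The first question was how many of the endocrine cells were beta cells after STZ. Beta cells made up 25.8% ± 13.7 of endocrine cells after STZ with implants (SD, n = 8) and 83.4% ± 11.6 in controls (SD, n = 3). The difference of -57.6 percentage points had an exact two-sided permutation p of 0.0121. Shares after STZ ran from 9.57% in STZ_M2 (exact interval 4.47% to 17.4%) to 52.7% in STZ_M5 (43.7% to 61.6%), below the lowest control at 72.4% (65.5% to 78.6%). Without implants at month 2 the shares were 6.67% and 26.2%. In the postnatal libraries they were 71.6% in P3, 84.9% and 90.5% in P12, and 47.8% in P21 (41.1% to 54.5%). The share in P21 thus lay within the range of the implanted STZ libraries. When cells were clustered again without the genes called between STZ and control, an alternative chosen after seeing the data, the difference was -57.5 points. Cells were sorted by their fluorescence and moved singly into lysis buffer, per the labels' protocols, so the shares describe the cells collected. With the batch number of the labels as a replicate block the permutation p was 0.0625, the smallest that 16 arrangements can give.

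**Figure D1:**
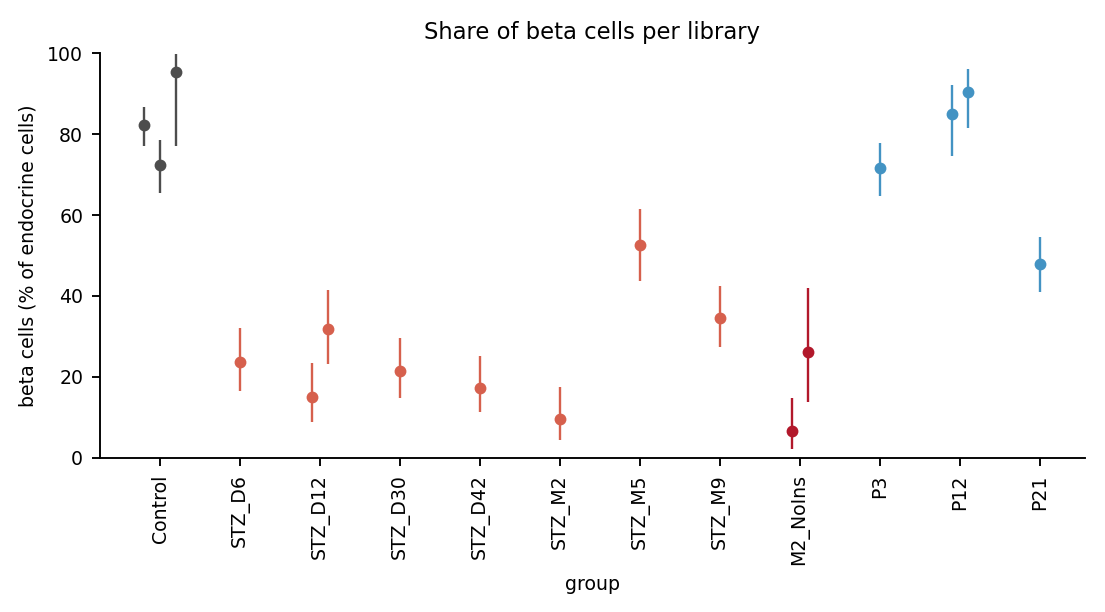
Share of beta cells among beta, alpha, delta and PP cells (%) in each library, by group. Points are libraries and bars exact 95% intervals; the 8 implanted STZ libraries lie between 9.57% and 52.7%, and the 3 controls between 72.4% and 95.5%.

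The main comparison asked which genes differed in the remaining beta cells after STZ with implants. Genes of the mature beta cell fell in all 8 STZ libraries. Ucn3, a peptide hormone of mature beta cells, fell by 3.25 ± 0.37 on the log2 scale (9.51-fold lower), from 9.55 ± 0.24 log2 CPM (SD, n = 3) to 6.04 ± 0.89 (SD, n = 8). Slc2a2, the glucose transporter GLUT2 through which STZ enters beta cells, fell by 3.01 ± 0.29 (8.04-fold lower). In the same libraries, Slc5a10, a sodium-coupled sugar transporter, rose 124-fold (log2 6.95 ± 0.46). Dlk1, a Notch-related protein of progenitor and young endocrine cells, rose 43.4-fold. Of 10707 genes tested with edgeR, 305 were called, 169 higher and 136 lower after STZ.

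Among the beta-cell maturity genes, 10 of 15 fell and 0 rose, and 11 fell adjusted over the list alone. Besides Ucn3 and Slc2a2, these included Trpm5, a cation channel (log2 -3.82 ± 0.34), and Cox6a2, a subunit of cytochrome c oxidase (-3.71 ± 0.65). Also among them were Sytl4, a protein of insulin granules (-2.17), Slc30a8, the zinc transporter of insulin granules (-1.77), and Prlr, the prolactin receptor (-1.60). The list was lower after STZ (camera adjusted p = 1.66e-14; adjusted p = 0.0201 with an estimated correlation). The glucose sensing and secretion machinery was lower too (adjusted p = 0.00146, and 0.0201 with an estimated correlation). Of its 23 members 6 fell, Pcx, or pyruvate carboxylase, among them (-1.50), and 1 rose, Tmem27, a membrane protein of beta cells (1.37). Adjusted over the list alone, 7 fell and 1 rose. Some of its members stand in the maturity list as well, Slc2a2, Trpm5 and Prlr among them. Gad1, which makes the transmitter GABA and is in no list, had the largest fall named here (-4.50 ± 0.56, 22.7-fold lower).

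The insulin genes moved less than these. Ins1 was at log2 -0.94 ± 0.25 (adjusted p = 0.0517) and Ins2 at -0.31 ± 0.20 (adjusted p = 0.616), so neither passed. Iapp, islet amyloid polypeptide, was at 0.03 ± 0.18 (adjusted p = 0.983), and its sign changed under several alternatives. Single cells held at most 8718 UMIs of any gene, and Ins2 counts rose little with the depth of the cell (slopes of 0.140 to 0.234 in controls). Of the 21 beta-cell transcription factors, 2 fell (2 adjusted over the list alone, where 1 other rose). Nkx6-1 fell by 1.29 ± 0.23 and Neurod1 by 0.68 ± 0.16. Pdx1 was at -0.71 ± 0.27 (adjusted p = 0.207). The list as a whole was not called (adjusted p = 0.387). Within insulin granule and hormone processing, Chgb, or chromogranin B, rose (1.66 ± 0.24), and 2 of 21 members rose while 3 fell. Adjusted over the list alone, 6 rose and 4 fell, and the list was not called (adjusted p = 0.270).

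Of the 19 immature, progenitor and dedifferentiation genes, 7 rose and 0 fell, and 12 rose adjusted over the list alone. Among them were Dlk1 and Gast, the hormone gastrin (4.10 ± 0.61). Rbp4, a retinol carrier (2.68 ± 0.34), Tspan8, a tetraspanin (2.55 ± 0.27), Pyy, or peptide YY (2.19 ± 0.40), and Cd24a, a surface glycoprotein (1.77 ± 0.41), also rose. The list was higher after STZ (adjusted p = 1.34e-10, and 0.00104 with an estimated correlation). Sorcs2, a sorting receptor outside the lists, rose 31.5-fold. Slc5a10 and Sorcs2 lay above every control in each of the 8 STZ libraries.

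Markers of the other endocrine cells moved in the same libraries. Of 6 PP-cell genes 3 rose, Ppy (2.52 ± 0.40), Pyy and Tspan8, and 5 adjusted over the list alone (adjusted p = 1.13e-06, and 0.0201 with an estimated correlation). Of 8 delta-cell genes 2 rose, Rbp4 and Cd24a, and 7 adjusted over the list alone (adjusted p = 5.62e-08, and 0.0201 with an estimated correlation). Pyy, Tspan8, Rbp4 and Cd24a also stand in the immature, progenitor and dedifferentiation list. The lists thus share genes here and below and are not separate lines of evidence. Sst, the delta-cell hormone, was at 2.50 ± 0.77 (adjusted p = 0.1004) and Gcg, the alpha-cell hormone, at -0.42 ± 0.55 (adjusted p = 0.874). Of 12 alpha-cell genes 3 rose, Smarca1, a chromatin remodeller, among them (1.90 ± 0.41), and 1 fell. Adjusted over the list alone 5 rose and 1 fell, and the list's call was lost (adjusted p = 0.0529 with an estimated correlation). Beta cells in which Gcg, Sst, Ppy, Pyy or Prss2 reached 1000 per 100000 UMIs, a limit chosen after seeing the data, made up between 20.6% (STZ_M5) and 68.8% (STZ_D12 replicate 1) of beta cells in STZ libraries. In controls they made up 4.76%, 12.9% and 33.3%. Without these cells Slc5a10 stayed at 7.10, Ucn3 at -2.90 and Rbp4 at 3.45, all still called. Ppy was then at 1.02 (adjusted p = 0.441) and Pyy at 1.18 (adjusted p = 0.319), a fall that the removal of cells rich in them brings by construction.

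**Figure D2:**
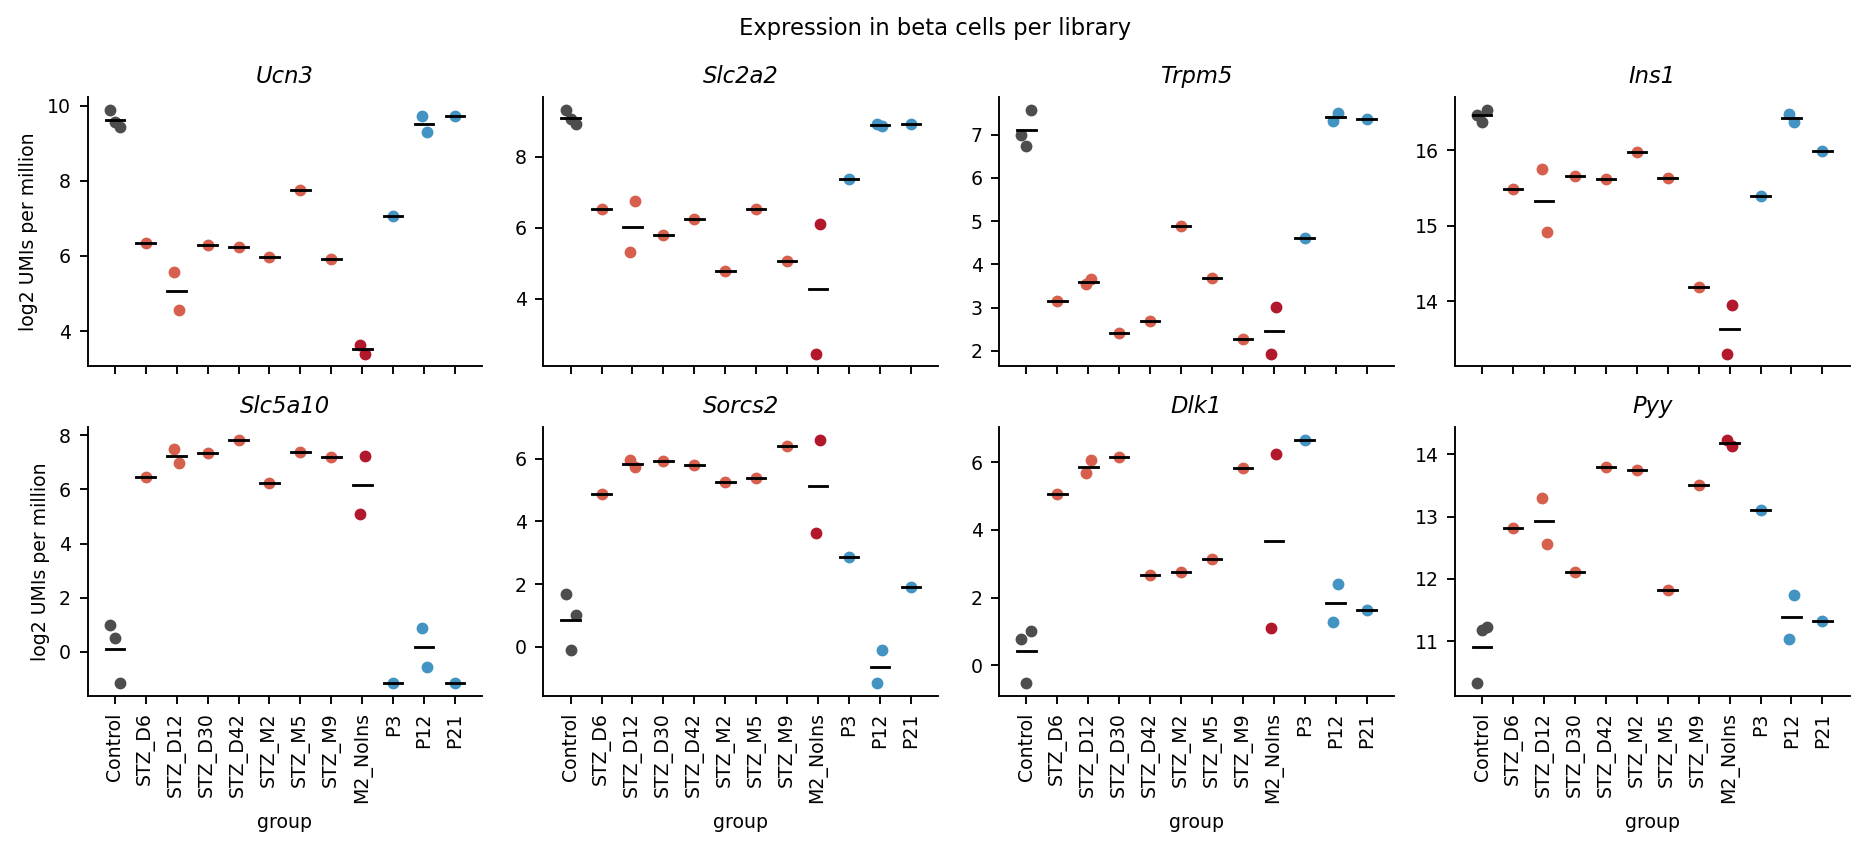
Expression of 8 genes in beta cells (log2 CPM, a log axis) in each library, by group. Points are libraries and lines group means; Ucn3 and Slc2a2 lie below, and Slc5a10 and Sorcs2 above, all 3 controls in each of the 8 implanted STZ libraries.

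Phlda3, a target of p53, rose by 4.57 ± 0.84 in 7 of 8 libraries and was the 1 of 22 p53 and DNA damage response genes to rise (3 adjusted over the list alone; adjusted p = 0.0257, and 0.345 with an estimated correlation). Of 25 oxidative stress response genes 2 rose, Gpx3, a secreted glutathione peroxidase (2.85 ± 0.42), and Txn1, or thioredoxin (0.75 ± 0.17). Adjusted over the list alone 4 rose and 2 fell (adjusted p = 0.0407, and 0.291 with an estimated correlation). Of 18 glycolysis genes 2 rose, Pdk1, which inhibits pyruvate dehydrogenase (1.54 ± 0.23), and Gpi1, an enzyme of the upper pathway (1.41 ± 0.20). Ldhb, a lactate dehydrogenase subunit, fell by 1.25 ± 0.24. Adjusted over the list alone 3 rose and 1 fell (adjusted p = 0.0199, and 0.0623 with an estimated correlation). Of 81 cytosolic ribosomal protein genes 0 were called by edgeR over all genes and 38 rose adjusted over the list alone, with a median of 0.38 (adjusted p = 1.55e-24, and 0.0530 with an estimated correlation). Oxidative phosphorylation had 1 of 78 members up and 2 down, the same counts adjusted over the list alone (adjusted p = 0.0257, and 0.670 with an estimated correlation).

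The other lists had 0 members called over all genes. The unfolded protein response (25 genes, adjusted p = 0.277), ATF4 and CHOP targets (22 genes, 0.266), cell division (22 genes, 0.279) and cholesterol synthesis (23 genes, 0.262) were not called, and 0 of their members passed adjusted over the list alone. Acinar-cell genes had a median of 1.13 over 25 members, 0 of them called over the list alone (adjusted p = 5.00e-06, and 0.404 with an estimated correlation). Ductal-cell genes (14 members, 0 adjusted over the list alone) had adjusted p = 0.00228, and 0.115 with an estimated correlation. Endothelial, stromal and blood-cell genes (7 members; 5 up and 1 down adjusted over the list alone) had 0.0407, and 0.345 with an estimated correlation. Antigen presentation and interferon response genes (23 members; 1 up adjusted over the list alone) had 0.00228, and 0.0929 with an estimated correlation. For genes disallowed in beta cells (9 members; 1 up adjusted over the list alone) the values were 0.0402, and 0.154 with an estimated correlation. Immediate early and dissociation genes (20 members, 0 adjusted over the list alone) were lower, with 0.00910, and 0.464 with an estimated correlation.

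The number of genes called depended on the controls. It was 109 without control replicate 1, 143 without replicate 2 and 159 without replicate 3, and 103 with the batch number as a block, 480 without a low-count filter and 603 with DESeq2. The share of called genes that were higher moved as well. It was 55.4% as planned, 68.5% with DESeq2, 48.8% with cells thinned to 1 depth, 47.6% with the batch block, 48.3% to 49.5% without single controls, and 34.6% with limma-trend (99 of 286) and with the mean of time-point means (79 of 228). Among the implanted STZ libraries whose sequencing run was given, which leaves out STZ_D12 replicate 2, STZ_D6, STZ_D30 and STZ_M2 had cells from a run that also held a control. In these libraries and control replicate 2, taken with all their cells, 8 genes were called, against 168 in the other STZ and control libraries. STZ_D6 and STZ_D30 also held cells from another run, so this was not a contrast within 1 run. These 2 alternatives were chosen after seeing the data.

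Next, each time point was set against the controls, to follow beta cells from day 6 to month 9. Ucn3 fell at day 6 (log2 -3.30 ± 0.44), day 12 (-4.59 ± 0.36), day 30 (-3.37 ± 0.45), day 42 (-3.40 ± 0.45), month 2 (-3.68 ± 0.48) and month 9 (-3.74 ± 0.45). At month 5 it was at -1.89 ± 0.40 (adjusted p = 0.0780). Slc5a10 rose at all 7 times, from 5.96 ± 0.73 at month 2 to 7.57 ± 0.64 at day 42. These and the other genes named in this paragraph, apart from Ucn3, Slc2a2 and Ins1, were chosen after their values were seen. At day 6, 7 genes were called, among them Trpm5 (-4.05), Rbp4 (2.48) and the p53 targets Phlda3 (6.27) and Ccng1, or cyclin G1 (2.40). Day 30 had 20 called genes, Txnip among them, a thioredoxin-binding protein induced by glucose (1.64). Day 42 had 38, with S100a6, a calcium-binding protein, at 3.10. Month 2 had 20, around a median of -0.32 over all genes, month 5 had 25 and month 9 had 68. Aldh1a3, an aldehyde dehydrogenase of dedifferentiated beta cells, rose by 4.91 ± 0.91 at month 5, with Txnip (2.06) and the fatty acid transporter Cd36 (5.69). At month 9, Cd36 (5.92), the gluconeogenic enzyme Fbp1 (7.09) and the peptide Cartpt (6.28) rose. Slc2a2 fell by 4.05 and Ins1 by 2.29 at month 9 (adjusted p = 0.0210 and 0.00809). At the other single-library times neither passed. Each of these time points but day 12 rests on 1 library, whose spread is assumed to be that of the replicated groups. Mice received STZ at 2 months of age, so time after STZ cannot be told apart from age here or in the trend below. Month 9 is also confounded with its discontinuous implants. The mean count of 29.7 genes over these 6 times became 17.3 without control replicate 2 and 16.7 without control replicate 3.

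The trend over time within the 8 STZ libraries, which asks whether genes drifted between day 6 and month 9, called 0 of 10134 genes with edgeR. At unadjusted p under 0.05 there were 336, and DESeq2 called 15 and limma-trend 2. With the batch number as a block 13 genes were called, 3 of them higher, and 3 were called in libraries with at least 20 beta cells. Per doubling of days, Ucn3 was at 0.24 ± 0.12, Slc2a2 at -0.14 ± 0.10 and Ins1 at -0.08 ± 0.10, and the last turned to 0.08 without month 9. The count was 2 without STZ_D12 replicate 1 and 1 without STZ_M2 or without STZ_M9. With the rank of time, which does not depend on whether STZ_D6 was day 6, 0 genes were called. Of 13 cell division genes 6 fell with time adjusted over the list alone (adjusted p = 2.33e-09, and 0.589 with an estimated correlation). Acinar-cell genes were lower with time in the same libraries, 1 of 25 over the list alone (adjusted p = 0.0371, and 0.844 with an estimated correlation). The p53 and DNA damage response (22 genes, 0 over the list alone; adjusted p = 0.000754, and 0.589 with an estimated correlation) and ATF4 and CHOP targets (22 genes, 0 over the list alone; adjusted p = 0.0371, and 0.844 with an estimated correlation) were lower too.

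Day 12, the only implanted time with 2 libraries, gave 85 called genes of 13560, 47 higher and 38 lower. Slc5a10 (6.97 ± 0.60), Dlk1 (6.01 ± 0.88), Sorcs2 (5.05 ± 0.74) and Phlda3 (4.50 ± 0.79) rose. Gad1 (-6.42 ± 0.58), Cox6a2 (-5.22 ± 0.63), Ucn3 and Trpm5 (-3.57 ± 0.41) fell. Of 16 maturity genes 10 fell (11 adjusted over the list alone; camera adjusted p = 2.60e-14, and 0.0644 with an estimated correlation). They included G6pc2, a glucose-6-phosphatase of islets (-2.84), Slc2a2 (-2.86), Slc30a8 (-2.22), Prlr (-1.99), Ppp1r1a, a phosphatase inhibitor (-1.94), and Ero1lb, an oxidase that folds proinsulin (-1.76). Of 24 immature, progenitor and dedifferentiation genes 6 rose (10 adjusted over the list alone; adjusted p = 1.51e-07, and 0.0644 with an estimated correlation), among them Rbp4 (2.43) and Tspan8 (2.56). Endothelial, stromal and blood-cell genes were higher in the same libraries (6 of 19 over the list alone; adjusted p = 4.65e-05, and 0.167 with an estimated correlation), and replicate 1 held 30 immune cells. Delta-cell genes were higher too (4 of 11 over the list alone; adjusted p = 0.000231, and 0.149 with an estimated correlation). Under TMM without hormone genes, alpha-cell (camera adjusted p = 0.00713) and ductal-cell genes (0.00354) were higher. So were genes of cytosolic ribosomal proteins (1.34e-12), antigen presentation and interferon response (0.000293), cell division (0.00123) and the p53 and DNA damage response (0.00534). Immediate early and dissociation genes (0.00134) and the glucose sensing and secretion machinery (0.00428) were lower. With an estimated correlation 0 of 23 lists were called. Of 10 PP-cell genes 3 rose, Ppy (2.42) and Pyy (2.01) among them (4 adjusted over the list alone; 0.00123, and 0.121 with an estimated correlation). Gpx3 (2.71) and Txnip (1.67) rose among 27 oxidative stress response genes (2 adjusted over the list alone; 0.112 by camera). Chgb rose by 1.97. Of 27 acinar-cell genes 2 rose, the digestive enzymes Cela2a (4.21 ± 0.87) and Prss3 (3.58 ± 0.62; 2 adjusted over the list alone; 7.12e-06, and 0.440 with an estimated correlation). The histone gene Hist1h2ap was called at 3.97 ± 0.86. Without STZ_D12 replicate 1 it was at 0.98 (adjusted p = 1.00), and Cela2a and Prss3 (3.24 and 2.19), Slc2a2, G6pc2, Slc30a8, Prlr, Ero1lb, Ppy and Pyy no longer passed. Without replicate 2 the same held for Phlda3, Chgb and Txnip. Ins1 was at -1.07 ± 0.27 (adjusted p = 0.1004) and Ins2 at -0.34 ± 0.23 (0.761). The count was 41, 34 and 24 without control replicates 1, 2 and 3, and 30 and 48 without STZ_D12 replicates 1 and 2. It was 21 with the batch block and with limma-trend (4 of them higher in the latter), 209 with DESeq2 and 329 without a filter, and 168 in libraries with at least 20 beta cells, which leaves 1 library at day 12.

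**Figure D3:**
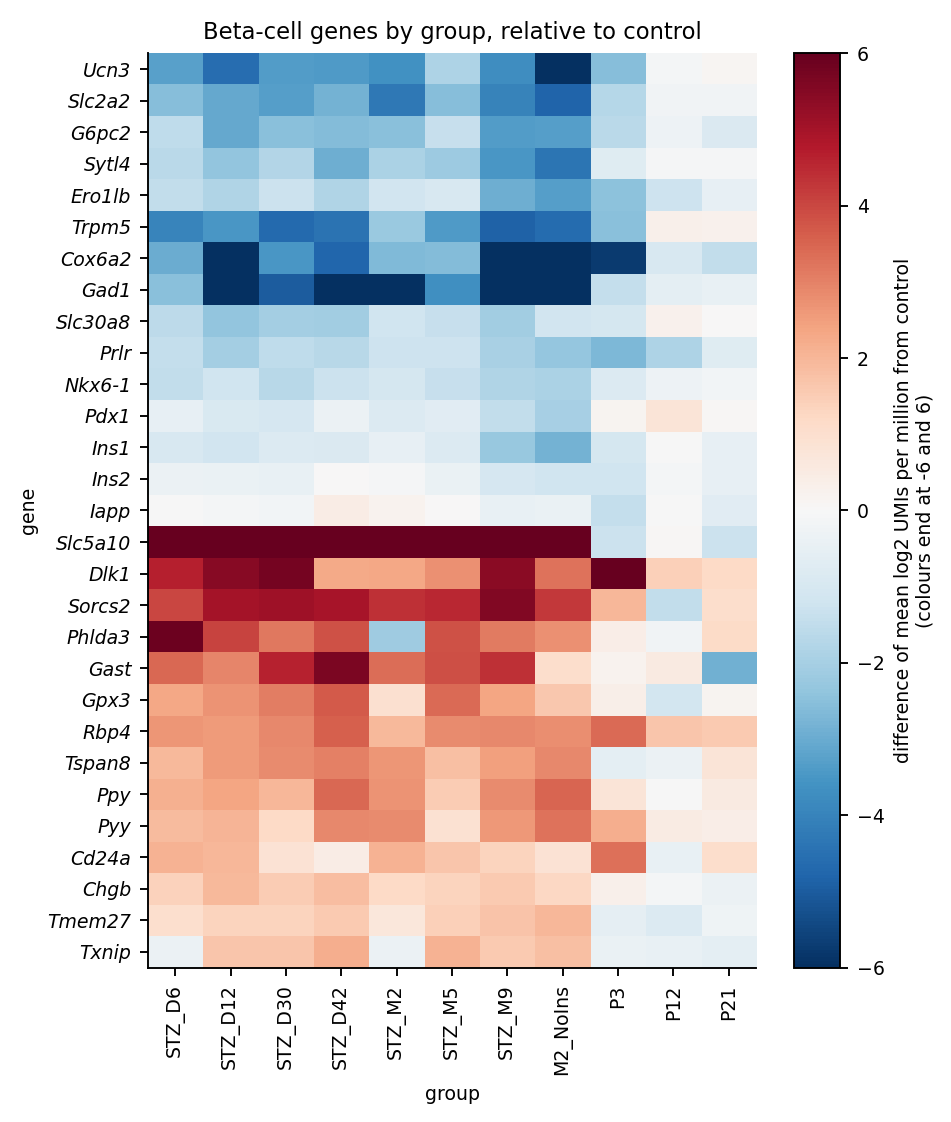
Difference of mean log2 CPM in beta cells between each group and the 3 controls, for 29 genes; colours end at -6 and 6. Ucn3 lies between -6.12 (STZ_M2_NoIns) and -1.87 (STZ_M5) in the STZ groups, at -2.57 in P3, -0.12 in P12 and 0.10 in P21.

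Insulin implants were absent from the 2 libraries of STZ_M2_NoIns, which allows beta cells without implants to be set against controls. The fall of mature genes in these summed cells included insulin itself. In replicates 1 and 2 Ppy stood at 14.79 and 14.25 log2 CPM, above Ins1 at 13.30 and 13.95. A change of beta cells cannot be told apart here from transcripts of other cell types. Ins1 fell by 2.80 ± 0.29 (6.98-fold lower), from 16.46 ± 0.08 log2 CPM (SD, n = 3) to 13.63 ± 0.46 (SD, n = 2), and Ins2 by 1.21 ± 0.24 (2.31-fold lower). Ucn3 fell by 6.20 ± 0.42 (73.3-fold lower). The transcription factors Pdx1 (-1.94 ± 0.43) and Nkx6-1 (-1.83 ± 0.39) fell, 2 of 22 in their list (2 adjusted over the list alone; adjusted p = 0.991 by camera). Iapp was at -0.40 ± 0.21 (adjusted p = 0.350). Of 13560 genes, 299 were called, 130 higher and 169 lower, around a median of -0.21 over all genes. The larger part turned under other settings, with 162 of 307 higher by RLE scaling, 335 of 608 by DESeq2, 158 of 297 by limma-trend and 192 of 371 without STZ_M2_NoIns replicate 1.

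Of 16 maturity genes 10 fell (12 adjusted over the list alone; adjusted p = 8.86e-10, and 0.143 with an estimated correlation), Sytl4 (-4.14), Slc2a2 (-3.83), Ero1lb (-3.33) and G6pc2 (-3.21) among them. Slc2a2 was at 2.46 log2 CPM in replicate 1 and 6.10 in replicate 2, and its log2 fold change was -3.01 without the first and -6.74 without the second. Gad1 had 0 UMIs without implants and was at least 49.7-fold lower, and the heat shock gene Hspa1a at least 36.5-fold lower. Cox6a2 had 3 UMIs, a ratio of 0.00720 (0.00148 to 0.0210). Of 25 unfolded protein response genes 2 fell, the chaperone Calr (-1.33) and Derl1, which exports misfolded proteins (-1.43; 4 adjusted over the list alone; adjusted p = 0.0501). Of 26 ATF4 and CHOP targets 2 fell, the folate enzyme Mthfd2 (-2.96) and asparagine synthetase Asns (-1.61; 8 adjusted over the list alone; 0.00693, and 0.461 with an estimated correlation). Of 24 immature, progenitor and dedifferentiation genes 8 rose (9 adjusted over the list alone; 3.64e-05, and 0.143 with an estimated correlation). Among them were Fev, a transcription factor of endocrine progenitors (4.42 ± 0.73), and Tspan8 (3.02). Dlk1 was called at 5.46 ± 0.91 but stood at 1.10 log2 CPM in replicate 1 and 6.25 in replicate 2, and at a log2 fold change of 0.92 without the latter (adjusted p = 0.750). Slc5a10 rose 77.5-fold, the tetraspanin Cd9 10.6-fold and Tmem27 4.16-fold. Of 10 PP-cell genes 4 rose, Ppy (3.45 ± 0.43) and Pyy (3.22 ± 0.31) among them (5 adjusted over the list alone; 0.000585, and 0.143 with an estimated correlation). Of 27 oxidative stress response genes 3 rose, Gpx3 (1.87), Txnip (1.78) and Gstm1, a glutathione transferase (1.41; 5 rose and 1 fell adjusted over the list alone; 0.0567). Gcg was at 1.74 ± 0.47 (adjusted p = 0.0682). Alpha-cell genes were higher (6 of 15 up and 1 down over the list alone; adjusted p = 0.00316, and 0.341 with an estimated correlation). Under TMM without hormone genes, endothelial, stromal and blood-cell genes were higher too (camera adjusted p = 0.0289). So were genes of cytosolic ribosomal proteins (4.32e-18), oxidative phosphorylation (0.000998) and cholesterol synthesis (0.00594). With an estimated correlation 0 of 23 lists were called. Without STZ_M2_NoIns replicate 1, Ins2, Pdx1, Nkx6-1, Calr, Derl1 and Gstm1 no longer passed, and without replicate 2 Asns and Gpx3 no longer did. These libraries held 5 and 11 beta cells, of which 5 and 9 reached that limit for Gcg, Sst, Ppy, Pyy or Prss2. Without such cells, which leaves 2 cells of 1 library, 96 genes were called around a median of -1.74 over all genes, so that fit was not used to judge single genes. The count was 133, 124 and 120 without control replicates 1, 2 and 3, 1781 without STZ_M2_NoIns replicate 2, 118 with the batch block, 608 with DESeq2 and 670 without a filter.

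Month 2 was the only time sampled with and without implants. Ins1 was lower without implants (log2 -2.32 ± 0.33) and Ero1lb by 4.49-fold (-2.17 ± 0.32). Prss53, a protease of beta cells, was 8.04-fold lower (-3.01 ± 0.53). Il6st, a cytokine receptor subunit, had 0 UMIs without implants and was at least 26.3-fold lower, the growth factor Hbegf at least 23.9-fold lower and Xk, a membrane protein, at least 13.5-fold lower. Il6st stood higher in STZ_M2 (6.11 log2 CPM) than in the other implanted libraries (2.43 to 4.41), and against all implanted times it was not called (adjusted p = 0.0604), while Hbegf and Xk were. Txnip (2.15 ± 0.39), Ttr, or transthyretin (2.54 ± 0.42), and Entpd3, an ectonucleotidase (2.66 ± 0.48), were higher. In STZ_M2, Ttr (9.75 log2 CPM) and Entpd3 (4.89) lay below all other implanted libraries and Txnip (8.12) below those from day 12 on. Against all implanted times none of the 3 was called (Txnip 0.59, Ttr 0.64 and Entpd3 0.62). Rasd1, a small GTPase, had 1 UMI with implants, a ratio of 42.3 (7.42 to 1687), and its log2 fold change of 5.13 became 2.45 against all implanted times. Without STZ_M2_NoIns replicate 1, Ins1 and Prss53 no longer passed (adjusted p = 0.0755 for each). Ucn3 was at -2.52 ± 0.52 (adjusted p = 0.110), Ins2 at -1.11 ± 0.30 (0.188), Gcg at 3.16 ± 0.76 (0.179) and Ppy at 0.83 ± 0.58 (0.582). Of 13560 genes 13 were called, 5 higher and 8 lower, among them 2 of 16 maturity genes (8 fell adjusted over the list alone; adjusted p = 0.00262, and 0.840 with an estimated correlation). Acinar-cell genes were lower in the same comparison, with a median of -2.20 and 7 of 27 lower over the list alone (adjusted p = 3.16e-06, and 0.840 with an estimated correlation), as were ATF4 and CHOP targets (4 of 26 over the list alone; adjusted p = 0.000615, and 0.840 with an estimated correlation). The implanted group is 1 library of 9 beta cells. The count was 25 and 938 without STZ_M2_NoIns replicates 1 and 2, 1 with the batch block and 2 among genes with an average of at least 4 log2 CPM. It was 20 against day 42 and months 2 and 5 pooled, 25 against all implanted times (15 of them higher), 85 with DESeq2, 184 without a filter and 357 with limma-trend.

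Postnatal beta cells were compared with adult controls as a measure of maturation. Hapln4, a matrix link protein (-2.58 ± 0.34), Serpini1, or neuroserpin (-2.14 ± 0.28), and Gsn, or gelsolin (-1.89 ± 0.28), were lower in all 4 postnatal libraries. Atp11a, a lipid flippase, was higher in all 4 (1.59 ± 0.21). Ucn3 was at -0.36 ± 0.45, Slc2a2 at -0.45 ± 0.32, Ins1 at -0.32 ± 0.28 and Ins2 at -0.39 ± 0.28, none of them called. The beta-cell maturity list was lower under TMM without hormone genes (camera adjusted p = 0.0319). With an estimated correlation 0 of 23 lists were called. Of 12608 genes 5 were called, 1 higher and 4 lower. Insulin granule and hormone processing had 8 of 21 members lower adjusted over the list alone (camera adjusted p = 6.45e-06, and 0.641 with an estimated correlation). Cell division genes were higher by camera, with a median of 1.73 and 0 of 29 members called over the list alone (adjusted p = 2.55e-08, and 0.641 with an estimated correlation). ATF4 and CHOP targets were lower, 4 of 23 of them over the list alone (adjusted p = 2.19e-05, and 0.641 with an estimated correlation). Acinar-cell genes were lower too, with 1 of 26 up and 2 down over the list alone (adjusted p = 2.66e-05, and 0.641 with an estimated correlation). Set against the controls one by one, with arms of 1, 2 and 1 libraries, P3 alone gave 79 called genes and P12 alone 86, and P21 alone gave 1, Prss1, a trypsinogen chosen after its values were seen. The count was 0 without control replicate 1 or 3, 2 without control replicate 2, 3 and 1 without P12 replicates 1 and 2, 135 without P21 and 0 with the batch block. DESeq2 called 233, limma-trend 65 and no filter 312. Beta cells that reached the limit for Gcg, Sst, Ppy, Pyy or Prss2 made up 58.9% of those of P3, 9.68% and 22.4% of P12 and 52.3% of P21. Without them 5 genes were called, Hapln4 (-2.78) and Atp11a (1.63) among them, while Serpini1 (adjusted p = 0.156) and Gsn (adjusted p = 0.123) no longer passed. With beta cells from the clustering without the called genes, in which P3 held 12 beta cells in place of 141, 0 were called. These 2 alternatives were chosen after seeing the data.

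Within the postnatal libraries, P12 and P21 together against P3 called 33 genes, 4 higher and 29 lower. P3 is 1 library, so the spread in this fit came from P12 and P21 alone, with 2 residual degrees of freedom, and age cannot be told apart from that library. Dlk1 was lower than in P3 (-5.04 ± 0.43), and Cox6a2 (4.82 ± 0.65) and Trpm5 (2.78 ± 0.38) were higher. Ucn3 was at 2.52 ± 0.42 (adjusted p = 0.0540) and Slc2a2 at 1.49 ± 0.36 (adjusted p = 0.180). These 5 genes were chosen after their values were seen. Macrophage genes such as Csf1r (adjusted p = 0.0283) and C1qb (adjusted p = 0.0298), chosen in the same way, were also lower than in P3. Without second-type cells 150 genes were called, with Dlk1 (-5.10), Cox6a2 (4.31) and Trpm5 (2.39) still among them, while Csf1r (adjusted p = 0.582) and C1qb (adjusted p = 0.461) no longer passed. With the 12 P3 cells of the other clustering 876 genes were called, Dlk1 (-4.00), Cox6a2 (5.94) and Trpm5 (4.92) among them. To compare STZ with maturation, log2 fold changes were correlated across 10649 genes, which are not independent replicates. Pearson's r was -0.299 and Spearman's rho -0.222, and 6053 genes had opposite signs. Over 297 genes called after STZ r was -0.667, and 234 had opposite signs. Leaving out single libraries gave r between -0.318 and -0.260, and r was -0.208 without second-type cells and -0.242 with the other clustering, both chosen after seeing the data. With shared controls, the fold changes of STZ and of all postnatal libraries had r = 0.309, and 20 simulated sets with no change gave a mean r of 0.639. The covariance was 0.113, against 0.0924 in the simulated sets.

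**Figure D4:**
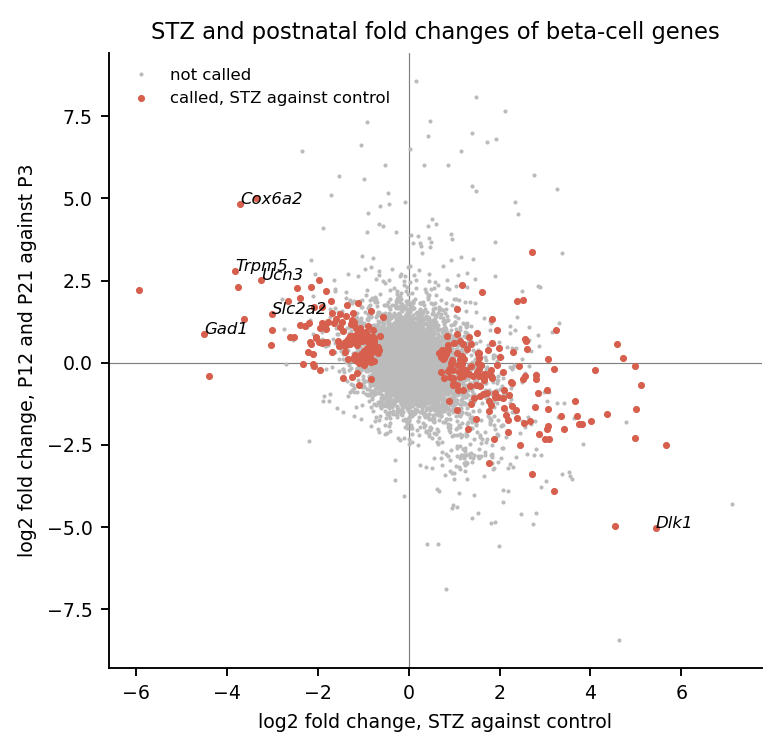
Log2 fold change of each gene in beta cells after STZ with implants (x axis) against that of P12 and P21 over P3 (y axis). Each point is 1 gene, coloured where called after STZ; Dlk1 (5.44 and -5.04), Cox6a2 (-3.71 and 4.82) and Trpm5 (-3.82 and 2.78) lie in opposite quadrants.

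The spread among beta cells within a library was measured by an identity score over maturity genes, at a fixed depth. Its mean was 6.42 ± 0.27 after STZ (SD, n = 8) and 8.22 ± 0.12 in controls (SD, n = 3), with an exact two-sided permutation p of 0.0121. The SD within libraries was 0.675 ± 0.206 after STZ (n = 8) and 0.571 ± 0.109 in controls (n = 3), with an exact permutation p of 0.461. With the interquartile range in place of the SD the difference was 0.497 (exact permutation p = 0.0121).

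Alpha cells of the same libraries had 0 of 11007 genes called by edgeR after STZ (8 libraries against 2), with 580 at unadjusted p under 0.05, 3 called by DESeq2 and 0 by limma-trend. Gcg was at 0.05 ± 0.26 (adjusted p = 0.992) and Ttr at -0.22 ± 0.32 (adjusted p = 0.986), both chosen after their values were seen. The sign of each changed when a control was left out. Camera called 10 of 23 lists in alpha cells, and 0 with an estimated correlation. Under TMM without hormone genes, acinar-cell genes (camera adjusted p = 4.73e-06) and ATF4 and CHOP targets (4.97e-05) were higher. So were ductal-cell (0.0116) and delta-cell genes (0.032), the unfolded protein response (0.0116) and genes disallowed in beta cells (0.0116). Antigen presentation and interferon response (0.0184) and cell division genes (0.0259) were higher as well. Beta-cell maturity genes (0.0259) and immediate early and dissociation genes (0.00165) were lower. The difference of the STZ effect between beta and alpha cells was tested within libraries, 7 of STZ and 2 controls, and was called for 25 of 12168 genes. STZ_M2, with 9 beta cells, was left out. In 19 of the genes the change was higher in beta cells and in 6 lower, while with limma-trend it was higher in 41 of 124. Sorcs2 (5.50 ± 0.60), Rbp4 (2.71 ± 0.43), Gpx3 (2.60 ± 0.43) and Chgb (1.58 ± 0.28) rose more in beta cells. Slc30a8 (-1.76 ± 0.28) and B2m, a chain of the class I complex (-2.15 ± 0.34), had lower changes in beta cells. The count was 1 without control replicate 1, 4 without control replicate 2 and 14 without STZ_D12 replicate 2. It was 11 with the batch block, 142 with DESeq2 and 199 without a filter.

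Of 72 genes looked up for these comparisons, 71 were found by symbol in the annotation of GRCm38, where positions count from 1. Ucn3 lies on chromosome 13 at 3940688 to 3945349, Slc2a2 on chromosome 3 at 28697903 to 28731359, and Trpm5 on chromosome 7 at 143069153 to 143094642. Slc5a10 lies on chromosome 11 at 61672781 to 61720826 and Dlk1 on chromosome 12 at 109452823 to 109463336. Ppy (102099930 to 102101319) and Pyy (102106676 to 102107832) are neighbours on chromosome 11, and Ins1 lies on chromosome 19 at 52264297 to 52265476. All are annotated as protein-coding genes. Reads behind each UMI are not given, so the intervals above cover counting error only.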

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

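The tests of other splits, of free RNA, of second cells and of the UMI ceiling were chosen only after the results were seen, and so was the fit of libraries with and without 1 sequencing run; the prediction for that run was written before its value was seen. The limit under which the second-cell explanation would have been excluded was also lowered to 10% after its value was seen, which left that explanation open.

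Among 48 groups of 4 to 10 libraries, 4 of 96 ends lay far from the others by Dixon's ratio, which chance alone gives in about 1 in 20 groups. Phlda3 in beta cells of STZ_M2 was at -1.169 log2 CPM, against 4.085 to 6.866 in the other STZ libraries; that library has 9 beta cells. Gcg in beta cells of STZ_M9 was at 12.77, against 9.646 to 11.02. Among the postnatal libraries, P3 was far below the others in Ucn3 (7.064 against 9.302 to 9.728) and in Slc2a2 (7.377 against 8.853 to 8.908).

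The effect of STZ differed between beta and alpha cells for 25 genes in a test of the difference itself. Named among them, as beta minus alpha on the log2 scale, were Sorcs2 (5.502), Serpina7 (2.857), Rbp4 (2.71), Gpx3 (2.603), Gria2 (1.866), Chgb (1.577), Tmem27 (1.246), Slc30a8 (-1.759), B2m (-2.148) and Rasd1 (-2.694). In a separate measure, the plain difference of mean log2 CPM between STZ and control libraries, B2m was at -0.71 in beta and 1.44 in alpha cells and Sorcs2 at 4.80 and -0.42; these need not add up to the fitted differences. Only 2 controls had enough alpha cells, and the count was 1 without control replicate 1 and 4 without control replicate 2.

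Cell classes used in no comparison made up more of the cells in some STZ libraries than of the pooled control cells. The upper limit given here is an exact binomial limit over control cells pooled from 3 libraries. It takes cells as the unit and leaves out the spread between libraries, so the shares were not tested over libraries. Immune cells made up 13.76% of cells in STZ_D12 replicate 1 (30 of 218) and 3.333% in STZ_D42 (8 of 240), against 1 of 587 control cells (0.1704%, upper limit 0.9455%). They made up 2.033% in STZ_D6 (5 of 246), 1.099% in STZ_D12 replicate 2 (2 of 182) and 0.6536% in STZ_M5 (1 of 153), and numbered 0 in STZ_D30, STZ_M2 and STZ_M9. Cells of the unnamed cluster made up 4.587% in STZ_D12 replicate 1, 3.249% in STZ_D30 and 7.5% in STZ_D42, and 1.587% to 2.762% in the other 5 libraries. That cluster was led by Dcn, Ccl2, Cp and the acinar-cell gene Amy2b. Its median UMI total was 2.49 times that of the libraries its cells came from. In most of its cells 7 markers of another class stood high, and 0 of its best-matching class, stromal. No biological explanation of these cells was tested.

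The first pattern weighed is the set of genes called between STZ and control beta cells. Of 100 splits of the 11 libraries into 8 and 3, drawn from 165, only the real 1 gave as many genes (305 against 31 in the highest other). This argues against a chance split, to the limit of 1 in 100 that these splits can reach. Splits that mix the arms carry their difference as spread, which lowers their counts. Sequencing runs differ between most STZ and control libraries, and the run of STZ_D12 replicate 2 is not given. In libraries without cells of the run of control replicate 2, 168 genes were called. Of 162 measured in the libraries with such cells, 161 had the same direction there (99.38%). These libraries were taken whole, and STZ_D6 and STZ_D30 also held cells of another run without a control. Only STZ_M2, with 9 beta cells, came wholly from the shared run. The test was therefore not made within 1 run and cannot exclude the run as a cause. STZ itself, with the loss of beta cells and the implants that go with it, stays open as a hypothesis. For libraries with cells from runs that hold no control or are not given, the changes stay confounded with the run.

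The second pattern is the rise of Pyy and Ppy in STZ beta cells. RNA released from other cells would reach beta and acinar cells alike, so the ratio to Gcg in beta over acinar cells would stay within the controls. For Pyy the median ratio was 3.321, and the ratio lay above both controls with acinar cells in 8 of 8 STZ libraries. Control replicate 3 had no acinar cells and so no ratio. Its scaled beta-cell medians were 116.4 for Pyy and 439.4 for Gcg. The Pyy median was lower in STZ_D6 (77.99), STZ_D30 (83.81), STZ_M5 (85.88) and STZ_D12 replicate 2 (116.3). In the other STZ libraries it was higher (201.7 to 827.9). The range of the controls thus rests on 2 libraries, and released RNA is not excluded for Pyy. For Ppy the median ratio was 1.657, and the ratio lay above both controls with acinar cells in 7 of 8 STZ libraries. Released RNA cannot be told apart from a change in the cells for Ppy, because 1 library lay within these controls. Up to 33.33% of beta cells in a library (3 of 9 in STZ_M2) held Pyy at 0.25 of the PP-cell median or more, so wells with a second cell could explain a part of the rise and cannot be told apart from cells with both hormones. A change of the beta cells toward PP-cell genes stays open and was not tested apart from this.

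The third pattern is the smaller fall of Ins2 than of Ins1. In controls the slope of log Ins2 UMIs on the log of the other UMIs of a cell was at most 0.2344, where proportional counting would give 1. For Iapp, with lower counts, the slopes were 0.476 to 0.726. A ceiling of UMI counts may therefore hide a part of any change of Ins2, and also of Ins1, whose slopes were 0.214 to 0.377. No biological explanation of the difference between the 2 genes was tested.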

How the results depend on the processing

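The limits of 10 cells, the beta cells without a second type's transcripts, the sequencing run, the clustering without the called genes and the average of at least 4 log2 CPM for the correlation were tests chosen only after the results were seen. Of 2875 values of 166 single-gene results under the alternatives, 2436 kept direction and side of the threshold, 345 no longer passed, 73 newly passed and 21 changed sign; 157 results never changed sign.

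Counts of called genes moved with the processing, and except where libraries, cells or tested genes were fewer by construction the cause was not tested. After STZ with implants 305 became 480 without a low-count filter, 603 with DESeq2, 103 with the replicate block, and 109 to 428 without single libraries. It was 8 in the libraries with cells of the run of control replicate 2 and 168 in those without. At day 12, 85 became 329 without a filter, 209 with DESeq2, 21 with limma-trend, 21 with the replicate block, 168 (1 library at day 12) and 300 with minimums of 20 and 10 cells, 190 without second-type cells and 24 to 48 without single libraries. Over the other time points the mean of 29.7 became 160.3 without a filter, 19.0 with an average of at least 4, 87.2 with DESeq2, 13.7 with the replicate block, 185.8 and 137.4 with minimums of 20 and 10 cells, 98.8 without second-type cells, and 16.7 to 20.2 without single controls. The trend's 0 by edgeR (336 at unadjusted p under 0.05) became 15 with DESeq2, 2 with limma-trend, 13 with the replicate block, 3 and 1 with minimums of 20 and 10 cells, and 0 to 2 without single libraries.

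Without implants against control, 299 became 670 without a filter, 608 with DESeq2, 118 with the replicate block, 96 without second-type cells (2 cells of 1 library), and 120 to 1781 without single libraries. Against month 2 with implants, 13 became 20 against 3 implanted times, 25 against all of them, 184 without a filter, 2 with an average of at least 4, 85 with DESeq2, 357 with limma-trend, 1 with the replicate block, and 25 to 938 without single libraries. In postnatal cells, 5 became 312 without a filter, 233 with DESeq2, 65 with limma-trend, 0 with the replicate block, 79, 86 and 1 for P3, P12 and P21 alone, 0 with the clustering without the called genes, and 0 to 135 without single libraries. In alpha cells the 0 by edgeR (580 at unadjusted p under 0.05; 0 by limma-trend) became 3 with DESeq2. For beta minus alpha, 25 became 199 without a filter, 142 with DESeq2, 124 with limma-trend, 11 with the replicate block, and 1 to 31 without single libraries.

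The correlation with maturation of -0.299 was -0.222 by Spearman, -0.667 over called genes, -0.343 with an average of at least 4, -0.208 without second-type cells, -0.242 with the clustering without the called genes, and -0.318 to -0.260 without single libraries. The difference in beta-cell share kept -57.6 with the replicate block, at exact permutation p = 0.0625, the smallest that 16 arrangements can give. The spread of the identity score passed only with the interquartile range (0.497). Of 69 list results past the threshold, 5 remained in number with an estimated correlation and 15 with fry. Of 23 lists each, camera called 17 after STZ, 14 at day 12, 4 in the trend, 9 without implants, 6 against month 2 with implants, 9 in postnatal and 10 in alpha cells; the 5 were all after STZ.

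These values changed sign, and the cause was not tested. After STZ, Iapp was at -0.117 with limma-trend, -0.0209 with the replicate block, -0.0500 with a minimum of 20 cells and without STZ_D12 replicate 1 and STZ_M2, -0.0016 without second-type cells, -0.0602 with all 10 STZ libraries, -0.0148 without the run and -0.0099 with the mean of time-point means; without single libraries it ran from -0.0422 to 0.0549. Gcg was at 0.56 with the replicate block, 0.0095 without second-type cells, 0.34 with all 10 STZ libraries and -1.04 to 0.460 without single libraries. Without single libraries, Ins2 at day 12 ran from -0.762 to 0.00551 and the Ins1 trend from -0.132 to 0.0827. For 1 setting each, Gstm1 without implants was at -0.300 without second-type cells, Ucn3 at 0.0833 for P21 alone, and Ins1 in STZ_M2 at 0.22 without second-type cells. In alpha cells, Gcg ran from -0.072 to 0.206 and Ttr from -0.509 to 0.163 without single libraries.

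Recovery in simulated counts differed between the designs. The changed genes had an average of at least 4 log2 CPM, so recovery at lower counts was not measured. Of 67 genes changed 4-fold, 65 were called in the design of STZ against control, 63 in the postnatal design, 56 in alpha cells, 51 at day 12 and 44 in the trend. Of 67 genes changed 2-fold, 33 were called in the design of STZ against control and 4 in the trend, so changes of that size could be missed. With cells thinned to 1 depth, 303 genes were called after STZ.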

Other observations

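The tests named here of other splits and of the clustering without the called genes were chosen only after the results were seen.

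Of 297 genes called after STZ and measured in P12 and P21 against P3, 234 had the opposite sign there, and 33 genes were called in that contrast as a whole. Slc5a10, with the largest rise among the named genes, was at -1.17 log2 CPM in P3 and P21, at 0.89 and -0.54 in P12, and between 6.24 and 7.84 in the implanted STZ libraries. Dlk1 rose both after STZ and in P3, by 6.26 in the difference of means between P3 and controls. Prlr was at -2.71 in P3 and -1.83 in P12 in the same measure. A candidate explanation is that the STZ state joins a loss of maturity to changes absent from young beta cells. The correlation with maturation was -0.299 over 10649 genes and -0.667 over the genes selected as called after STZ. No test separated the 2 sets of genes, so this explanation was not tested.

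Of the 35 splits of the 7 libraries, 2 gave 5 genes or more. They were the real split of postnatal and adult beta cells, with 5, and 1 other, with 122. Of the remaining splits the highest gave 2. The split with 122 set P3 and both P12 libraries apart from P21 and the controls. It therefore follows age in part and is no clean reference for chance, and a split that calls many genes points to a structure of the samples. Chance is not excluded for the count of 5.

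When cells were clustered again without the 305 genes called between STZ and control, 92.8% kept their class. With beta cells taken from that clustering 310 genes were called, 302 of them shared with the first. P3 held 141 beta cells in the first clustering and 12 in the second, and 19 and 185 delta cells. Its alpha cells went from 33 to 0 and its PP cells from 4 to 0. The class called delta in the second clustering therefore took in P3 cells of several classes.

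Pairs of libraries from different groups with the same batch number had a median correlation of 0.036 in their residual expression (12 pairs, -0.0996 to 0.108). Other pairs had -0.0205 (18 pairs). Residuals mirror each other in groups of 2 libraries, so the other pairs largely repeat values with the sign turned. They are no separate reference.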
